A study of Homo sapiens with 12 samples.

How the data were processed

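RNA from cultured NCI-H1975 cells, a human lung adenocarcinoma line that carries a mutant EGFR, was hybridised to 12 Affymetrix Human Gene 2.1 ST arrays, which read probes spread over the exons of each gene. The labels gave 1 untreated array with no time, 4 arrays of cells in 1 µM erlotinib (6, 12, 24 and 48 h), 3 arrays in 3 µM quinacrine (6, 12 and 24 h) and 4 arrays in both compounds (6, 12, 24 and 48 h). Each treatment and time had a single array, so the design had no replicates of a condition. The arrays of a treatment arm were treated as a group, and n below counts time points. Nothing in the labels says whether the arrays came from separate cultures, so p-values measure only the spread between these arrays.

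Per the labels and the series design text, the authors processed the scans with Affymetrix Expression Console 1.30 by RMA (background correction, quantile normalization across arrays and summary per probe set) and annotated the probe sets with hg19 files. The deposited values are log2 expression levels with 2 decimals, and they were used as deposited, with no further normalization. All 12 columns of the table were matched to samples by their labels. The table held 53617 rows, of which 23871 had 1 gene symbol, 1842 had several and 27904 had none in the platform annotation used here. Symbols of 22569 named rows were matched to current RefSeq names through Entrez IDs, and 90 of them changed. The named rows gave 22395 genes, 632 of them with several rows. Rows shared by several genes were not named.

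A gene was tested when its mean over all arrays was at least 5 on the log2 scale, with the row of the highest mean used where a gene had several. This left 5820 genes (26.0% of the named genes). The mean took in the treated arrays, so a gene low without treatment could pass through the arrays where it was high. Arrays carry no read depth; their number limits the precision, and the filter kept the genes whose signal stood clear of the array medians of 1.39 to 1.64.

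Tests were made with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the 5820 genes and a threshold of 0.05. The 3 treated groups were compared in 1 fit of the 11 treated arrays with treatment and time as factors, which left 5 residual degrees of freedom. The residual of that fit is the departure of the arrays from an additive effect of treatment and time, not replicate error. Each treated group was compared with the untreated array, and the departure from additivity (combination minus erlotinib minus quinacrine plus untreated) was tested, in a fit of group means over all 12 arrays with 8 residual degrees of freedom. There the lone untreated array was assumed to vary like the arrays of the treated groups. That fit had no time term, so changes with time within a treated group counted as spread. The trend with time was a slope per doubling of time shared by the 3 treated groups, and its difference between combination and erlotinib was tested on the 8 arrays of these groups.

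Before the data were examined, 29 gene lists were fixed, covering the FACT complex, NF-kappaB, the cell cycle, EGFR signalling, stress responses, metabolism and markers of other cell types. The 24 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative, and with fry. The rule for named genes was fixed at the same time. In each comparison it took the 6 largest rises and 6 largest falls past the threshold that went the same way at every matched time (3 of each with the smallest p where no gene passed). It added the 3 members with the smallest p of each called list and of the FACT, NF-kappaB, G1/S and G2/M lists. SUPT16H, SSRP1, EGFR, NFKB1, RELA, NFKBIA, CDKN1A, CCND1, CDK1 and MYC were always named. CDKN1A, at a mean of 3.99, lay below the filter and was not tested. The text names the genes of this rule most relevant to each comparison and, for some lists, the other members that passed; any gene chosen otherwise after its value was seen is marked.

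The procedure was tested on simulated arrays with the gene means and residual spreads of the real arrays, 200 of 5820 genes changed and no correlation between genes. For combination versus erlotinib it recovered 56.5% of genes changed 1.5-fold and 97% of genes changed 2-fold. For quinacrine versus erlotinib the shares were 18.5% and 91.5%, for combination versus quinacrine 18% and 95%, and for erlotinib versus untreated 2% and 54.5%. With no gene changed, no gene was called in any of these simulated comparisons, and camera at the preset correlation called 1 list of 24.

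Alternatives covered the filter, the rows used, the prior variance, cyclic loess and median centring of the arrays, array weights, a 1.5-fold threshold, the arrays and time points in the fit, the time term, the scale of time, the correlation in camera and leaving out each array in turn. After the data were seen, a fit without the combination 6 h and erlotinib 12 h arrays, camera on the time trends and between-array scaling of the gene lists were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.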

Results

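Gene expression was measured in H1975 lung adenocarcinoma cells left untreated or exposed to erlotinib, an EGFR kinase inhibitor, to quinacrine, an acridine antimalarial, or to both. The 12 arrays comprised 1 untreated array, 4 erlotinib arrays, 3 quinacrine arrays and 4 combination arrays, 1 for each treatment and time. No condition had a replicate. The title of the study asks about the histone chaperone FACT, NF-kappaB and progression through the cell cycle. The median correlation of an array with the others ranged from 0.955 to 0.981 over all rows. The combination 6 h array was lowest, with the smallest interquartile range of values (2.04, against 2.26 for the erlotinib 12 h array and up to 2.88 for the quinacrine 24 h array) and 7470 rows at a level of 5 or more, against up to 9169 elsewhere. Its median over the tested genes was 6.18, compared with 6.39 to 6.56 on the other arrays.

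**Figure D1:**
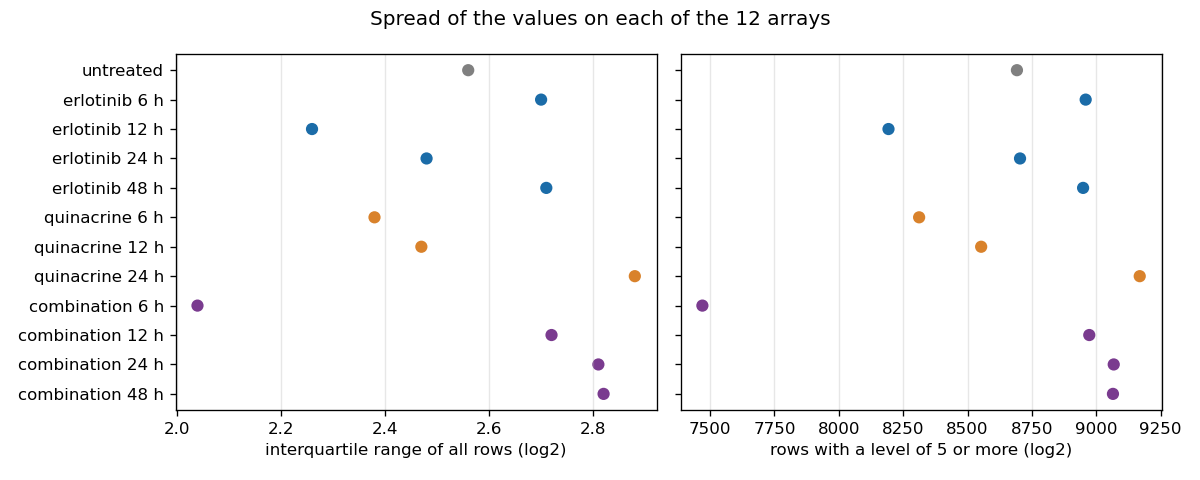
Spread of the log2 values on each of the 12 arrays. Left, interquartile range over all rows; right, number of rows at a level of 5 or more (the axis does not start at 0); each point is 1 array, coloured by treatment. The combination 6 h array has the lowest value in both panels (2.04 and 7470).

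The effect of quinacrine added to erlotinib was compared over 4 matched times. IL24, a cytokine of the interleukin-10 family, was 6.95-fold higher with the combination than with erlotinib alone (log2 difference 2.80, SE 0.30, limma adjusted p = 0.00672, n = 4 time points per group). ICAM1, an adhesion molecule that binds leukocytes, rose 2.88-fold (SE 0.13, adjusted p = 0.00182), from a level of 7.0 ± 0.32 (SD over time points, n = 4) with erlotinib to 8.53 ± 0.19 (SD, n = 4). The chemokine genes CXCL16 and CCL2 rose 4.17-fold and 3.19-fold, the galanin receptor gene GALR2 3.31-fold and PXDC1 3.20-fold. CXCL16, IL24, GALR2 and PXDC1 had mean levels below 5 in the erlotinib arrays (3.96, 4.57, 4.72 and 4.96). The largest falls were those of FAM83H (3.33-fold), MLLT1, a subunit of transcription elongation complexes (3.11-fold), INPP5A, an inositol polyphosphate 5-phosphatase (2.72-fold, SE 0.12, adjusted p = 0.00182), the cystine transporter gene SLC7A11 (2.69-fold), WNT9A (2.50-fold) and GALNT11 (2.46-fold). FAM83H, MLLT1 and WNT9A differed most at 6 h (-2.91, -2.65 and -2.33 log2) and least at 48 h (-0.82, -0.92 and -0.21). SLC7A11 differed by -0.74 at 6 h and by -2.15 at 24 h.

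**Figure D2:**
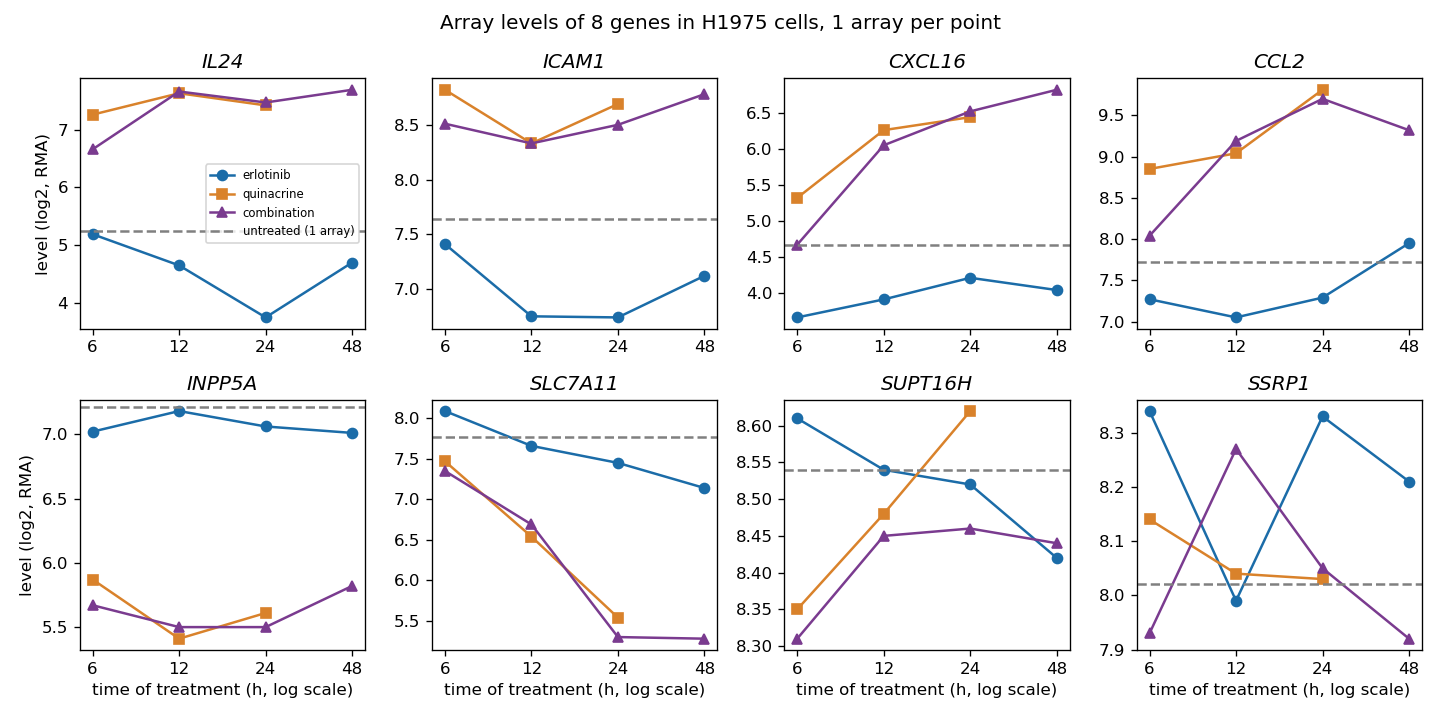
Levels (log2, RMA) of 8 genes against time of treatment (h, log scale), 1 array per point, with the untreated array as a dashed line and a separate vertical scale in each panel. IL24, ICAM1, CXCL16 and CCL2 lie higher and INPP5A and SLC7A11 lower in the quinacrine and combination arrays than in the erlotinib array of the same time, whereas SUPT16H and SSRP1, the FACT subunits, span less than 0.5 log2.

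Among the lists fixed in advance, NF-kappaB target genes and interferon-response genes were placed above the other genes by camera at its preset correlation. Of 18 tested NF-kappaB targets, 4 rose (ICAM1, CCL2, IRF1 and CXCL8), none fell and 14 did not pass, while 10 rose when adjusted over the list alone. The median log2 difference was 0.505 (camera adjusted p = 1.37e-08; adjusted p = 0.615 with an estimated correlation), and it was -0.085 at 6 h, 0.525 at 12 h, 0.75 at 24 h and 0.905 at 48 h. Of 17 interferon-response genes none passed singly, 4 rose when adjusted over the list alone, and the median was 0.803 (camera adjusted p = 4.4e-07; adjusted p = 0.615 with an estimated correlation). The list's median was -0.37 at 6 h, 0.45 at 12 h, 1.64 at 24 h and 1.12 at 48 h. List medians at single times are not set against the other genes. Over all tested genes the median against the untreated array was -0.21 on combination 6 h and 0.06 on erlotinib 6 h. At 12 h these medians were 0.08 and -0.06. Negative list medians at 6 h thus do not by themselves show a fall. IFITM1 differed by 0.94 (SE 0.24, adjusted p = 0.074) and IFI6 by 0.97 (SE 0.27, adjusted p = 0.0904). The EGFR/ERK output list, genes induced by that pathway, had 5 of 16 members up (the ephrin receptor gene EPHA2, the feedback inhibitors SPRY4 and DUSP5, SPHK1 and EGR1) and a median of 0.13, with -0.295, 0.235, 0.27 and 0.635 at 6, 12, 24 and 48 h. The FOXO list had 1 of 6 up, TXNIP, an inhibitor of thioredoxin, by 1.98-fold, with a median of 0.368. Camera adjusted p was 0.00703 for the EGFR/ERK list and 0.00563 for the FOXO list, and adjusted p = 0.615 with an estimated correlation for both. Without the erlotinib 48 h or the combination 48 h array the EGFR/ERK list had a median of -0.012 and was not called.

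**Figure D3:**
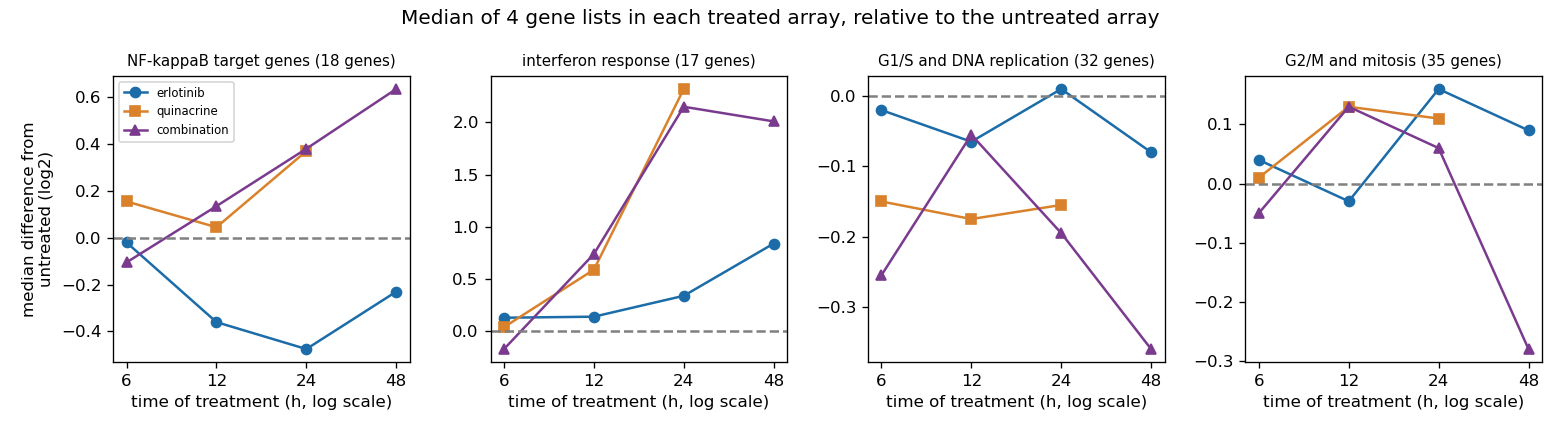
Median log2 difference from the untreated array over the tested genes of 4 lists, against time of treatment (h, log scale), 1 array per point, with a separate vertical scale in each panel. In the combination arrays the NF-kappaB list goes from -0.105 at 6 h to 0.635 at 48 h and the interferon list from -0.17 to 2.01, whereas in the erlotinib arrays the 48 h values are -0.23 and 0.84. The values are not corrected for the median over all tested genes, which was -0.21 on the combination 6 h array.

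Of the cell cycle lists, camera at its preset correlation placed G1/S and DNA replication below the other genes and did not call G2/M and mitosis. Of 32 genes of G1/S and DNA replication, CDT1, a replication licensing factor, fell 1.72-fold and CHAF1A, a subunit of a histone chaperone, 1.97-fold, and 30 did not pass; 4 fell when adjusted over the list alone. The list's median was -0.139 (camera adjusted p = 0.00563 at the preset correlation and 0.615 with an estimated correlation). Its values were -0.2, -0.065, -0.115 and -0.24 at 6, 12, 24 and 48 h. At 6 h the median over all tested genes against the untreated array was itself -0.21 with the combination and 0.06 with erlotinib. The 35 genes of G2/M and mitosis had a median of -0.13 and none passed (camera adjusted p = 0.0684), and KIF20A, a mitotic kinesin, differed by -0.67 (SE 0.16, adjusted p = 0.0589). The G2/M list was called without erlotinib 6 h (median -0.099), erlotinib 12 h (-0.192), combination 6 h (-0.112) or combination 12 h (-0.221), and without both combination 6 h and erlotinib 12 h (-0.194). Of 9 replication-dependent histone genes, H1-4 and H2AC21 fell, and the list's median was -0.31 (camera adjusted p = 0.05002). The FACT subunits SUPT16H (log2 difference -0.11, SE 0.10, adjusted p = 0.587) and SSRP1 (-0.17, SE 0.12, adjusted p = 0.476) did not pass. EGFR (-0.04), NFKB1 (-0.02), RELA (-0.04), NFKBIA (0.60), MYC (-0.01), CCND1 (0.20) and CDK1 (-0.23) did not pass either, with adjusted p from 0.211 for NFKBIA to 0.985 for MYC. CDKN1A, below the filter, was at 4.03, 3.95, 3.82 and 3.59 with erlotinib and at 3.97, 3.81, 4.08 and 4.64 with the combination at 6, 12, 24 and 48 h. Of the markers of other cells, CD68, HLA-DRA and CD74 were tested and did not pass (-0.36, -0.285 and -0.22).

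In all, 212 of 5820 genes differed between combination and erlotinib in the limma fit, 83 higher and 129 lower, each in the same direction at all 4 times, and 39 by at least 2-fold. A fit of the 8 erlotinib and combination arrays alone, matched by time, gave the same differences with fewer residual degrees of freedom and called 6 genes (3 higher and 3 lower). Of the 19 named genes that passed, 15 lost their call in it, IL24, CXCL16 and CCL2 among them, whereas ICAM1, PXDC1, INPP5A and GALNT11 passed. With no filter on the mean 51 genes were called, 9 over all rows of the table, and with only the 6, 12 and 24 h arrays 34. Array weights gave 202 higher and 178 lower. Cyclic loess scaling gave 225 higher and 236 lower, and median centring 223 and 216. Without the combination 6 h and erlotinib 12 h arrays the count was 168, with 89 higher and 79 lower. Without combination 6 h alone it was 294, with 177 higher and 117 lower. The excess of lower genes in the main fit thus did not hold without that array. Leaving out a single array gave 322 genes without erlotinib 6 h, 19 without erlotinib 12 h, 11 without erlotinib 24 h, 34 without erlotinib 48 h or combination 48 h, 66, 41 and 26 without quinacrine 6, 12 and 24 h, 31 without combination 12 h and 6 without combination 24 h. Of the 35 ways to regroup these 8 arrays, 22 made camera call at least 5 lists, as the real grouping did.

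Quinacrine alone and erlotinib alone differed in 66 genes, 30 higher and 36 lower with quinacrine, in the fit of all 11 treated arrays; the arrays of 6, 12 and 24 h alone gave 41 genes. IL24 was 7.67-fold higher (log2 2.94, SE 0.33, limma adjusted p = 0.00785, n = 3 quinacrine and 4 erlotinib time points), CXCL16 4.59-fold, CCL2 3.94-fold, GALR2 3.59-fold, ICAM1 3.18-fold and PXDC1 3.01-fold. FAM83H fell 3.51-fold, SNAR-E, a small noncoding RNA with near-identical gene copies, 3.49-fold, INPP5A 2.67-fold, BOK, a BCL2-family gene, 2.46-fold, RPUSD1 2.44-fold and NACC2 2.41-fold. The count was 28 with no filter on the mean and 3 over all rows of the table, and it was 152 higher and 166 lower with cyclic loess, 149 and 144 with median centring and 363 and 319 with array weights. Camera called 11 lists, and each was lost with an estimated correlation (smallest adjusted p = 0.563 with an estimated correlation). NF-kappaB targets had 3 of 18 members up and a median of 0.426, interferon-response genes 0 of 17 and 0.767, and EGFR/ERK output 2 of 16 and 0.222. The medians were 0.235 for cholesterol synthesis, 0.36 for apoptosis regulators, 0.204 for epithelial markers and 0.331 for FOXO targets, of which TXNIP rose. Lists lower with quinacrine were G1/S and DNA replication (median -0.096, 0 of 32 passed), histones (-0.272, H1-4 fell), amino acid and ATF4 response (-0.132, 0 of 18) and ER chaperones (-0.078, 0 of 15). Adjusted over the list alone, 5 NF-kappaB, 5 EGFR/ERK output and 3 apoptosis genes rose, and 6 ATF4-response and 4 ER chaperone genes fell. The cholesterol, apoptosis, epithelial, histone, ATF4-response and ER chaperone lists each lost their call without at least 4 of the arrays taken singly (camera adjusted p from 0.0516 to 0.2), and each array except quinacrine 6 h had such an effect on at least 1 of them; cyclic loess also ended the epithelial call. SUPT16H (-0.05, SE 0.11, adjusted p = 0.853) and SSRP1 (-0.17, SE 0.14, adjusted p = 0.58) did not pass. Leaving out a single array gave 257, 10, 9 and 41 genes without erlotinib 6, 12, 24 and 48 h, 4, 3 and 0 without quinacrine 6, 12 and 24 h, and 288, 32, 22 and 41 without combination 6, 12, 24 and 48 h.

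Erlotinib added to quinacrine gave no gene past the threshold in limma (smallest adjusted p = 1), and 47 genes had an unadjusted p under 0.05, fewer than the 291 that independent tests give by chance. The 95% interval of the difference lay within 1 log2 unit for 96.5% of all genes and for 99.5% of the 212 genes called between combination and erlotinib. The median half-width of the interval was 0.334. On simulated arrays this comparison recovered 18% of genes changed 1.5-fold. The absence of a call thus does not show that erlotinib added no effect to that of quinacrine. CYP1B1, a cytochrome P450, differed by 0.75 (SE 0.14, adjusted p = 1) and was higher with the combination at 6, 12 and 24 h by 0.47, 0.72 and 1.01. IGLJ7 differed by 1.03 and OXNAD1 by 0.38, and MAIP1, GINS4 and SAFB2 by about -0.4 (-0.42, -0.41 and -0.38). ICAM1 differed by -0.14 (SE 0.14), CCL2 by -0.31 (SE 0.27), SSRP1 by -0.01 (SE 0.14) and SUPT16H by -0.06 (SE 0.11). Camera called no list among 24.

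Against the untreated array, whose time in culture the labels do not give, no gene passed the threshold with erlotinib in limma (smallest adjusted p = 0.999), and 144 genes had an unadjusted p under 0.05. The fit had no time term, so changes with time within a treated group counted as spread. Independent tests give 291 genes with an unadjusted p under 0.05 by chance, more than the 144 found. The absence of a call thus does not show that erlotinib had no effect. Camera placed 5 lists lower with erlotinib than the other genes. These were NF-kappaB targets (median -0.319), EGFR/ERK output (-0.294), YAP and cell density (-0.185), mesenchymal markers (-0.147) and ribosome biogenesis (-0.14), with camera adjusted p from 0.00242 to 0.0336 and adjusted p = 0.674 with an estimated correlation. TNFAIP3, a feedback inhibitor of NF-kappaB, differed by -1.22 (SE 0.62), the YAP target CCN1 by -0.96 (SE 0.46) and EREG, an EGFR ligand, by -0.74 (SE 0.38). No member of these lists passed, also when adjusted over the list alone. Without the erlotinib 48 h array the ribosome biogenesis (-0.103), YAP (-0.165) and mesenchymal (-0.063) lists were not called; the mesenchymal list was not called either without combination 6 h or after cyclic loess or median centring (camera adjusted p = 0.0519, 0.0792 and 0.073). At least 1 log2 unit from the untreated array lay 5 genes at 6 h, 57 at 12 h, 41 at 24 h and 116 at 48 h of erlotinib.

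Against the lone untreated array, which serves both comparisons and was assumed to vary like the treated arrays, 2 genes were lower with quinacrine, INPP5A (2.99-fold, SE 0.19, limma adjusted p = 0.016) and H2AX, a histone variant phosphorylated at DNA breaks (2.39-fold, SE 0.16, adjusted p = 0.016), in all 3 arrays. With the combination INPP5A (3.01-fold) and H2AX (2.31-fold) were lower and PXDC1 (2.84-fold, SE 0.21, adjusted p = 0.0262) higher, in all 4 arrays. Over all rows of the table INPP5A and H2AX lost their call for quinacrine. There all 3 genes lost it for the combination, and the 1 gene called was another. With no filter, or only the 6, 12 and 24 h arrays, 1 lost its call for quinacrine and 2, PXDC1 among them, for the combination. Cyclic loess also ended 1 call for quinacrine. PXDC1 was not called either without erlotinib 24 or 48 h, quinacrine 6, 12 or 24 h, or combination 12 or 24 h. At least 1 log2 unit from the untreated array lay 153, 120 and 159 genes at 6, 12 and 24 h of quinacrine, and 451, 99, 152 and 177 at 6, 12, 24 and 48 h of the combination. The 451 genes of the combination 6 h array were 295 after the arrays were centred. Camera called no list for quinacrine and 6 for the combination: up were interferon response (median 1.20), NF-kappaB targets (0.251) and lysosome (0.203), and down were G1/S and DNA replication (-0.254), ER chaperones (-0.155) and heat shock (-0.297). Their camera adjusted p ran from 0.00219 to 0.0447, the smallest adjusted p was 0.634 with an estimated correlation, and no member passed; adjusted over the list alone, 1 NF-kappaB gene rose. Without combination 48 h the NF-kappaB (0.125), lysosome (0.142), ER chaperone (-0.13) and heat shock (-0.307) lists were not called, nor were the last 3 without combination 24 h (0.142, -0.14 and -0.302). Heat shock was not called either without erlotinib 6 h or combination 12 h, or after cyclic loess or median centring, and ER chaperones after cyclic loess (camera adjusted p between 0.0501 and 0.0566). Without the quinacrine 24 h array no gene was called for quinacrine, without quinacrine 6 h 1 and without combination 6 h 5; for the combination, no gene was called without combination 24 h and 5 were without combination 48 h. The 2 arrays with the smallest spread left out, 9 genes were called for quinacrine and 5 for the combination. Median centring gave 2 higher and 4 lower for quinacrine and 3 higher and 3 lower for the combination, array weights 226 higher and 268 lower for quinacrine and 504 higher and 305 lower for the combination, and all rows of the table gave 1 gene for the combination. The departure from additivity, a contrast of group means not matched in time, since quinacrine has no 48 h array, had no gene past the threshold in limma (smallest adjusted p = 1, 116 genes with an unadjusted p under 0.05). Its values were -0.05 (SE 0.17) for SUPT16H, -0.23 (SE 0.21) for SSRP1 and 0.63 (SE 0.55) for NFKBIA. With the 6, 12 and 24 h arrays no gene passed either. Independent tests give 291 genes with an unadjusted p under 0.05 by chance, and the median SE, 0.266, was the largest of all comparisons. No simulation was run for this contrast. The absence of a call thus does not show that the 2 compounds act additively.

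Interferon-response genes rose with time in a slope shared by the 3 treated groups. The lone untreated array has no time, so time of treatment cannot be told apart from time in culture. Of 17 tested members 11 rose, and all 17 did when adjusted over the list alone. The list has 29 genes with a row of their own, and the filter on the mean over all arrays kept these 17. IFI44L, for example, was at 4.19 on the untreated array and at 7.27 on combination 48 h. Members that stayed low were not tested, so the share that rose is partly set by the filter. The median slope was 0.586 log2 per doubling of time (camera adjusted p = 7.1e-12 at the preset correlation and 0.584 with an estimated correlation). OAS2 and XAF1, antiviral and pro-apoptotic interferon-induced genes, rose by 1.07 (SE 0.23, limma adjusted p = 0.0392) and 1.05 (SE 0.23, adjusted p = 0.0459) per doubling, and IFITM1, which blocks virus entry, by 0.81 (SE 0.10, adjusted p = 0.00558). DHRS3, a retinal reductase (0.87), IFI44L (0.85) and CFB, a complement factor (0.76), also rose. The interferon list's median against the untreated array reached 2.32 with quinacrine and 2.15 with the combination at 24 h, compared with 0.34 with erlotinib. At 6, 12, 24 and 48 h it was 0.13, 0.14, 0.34 and 0.84 with erlotinib. With the combination it was -0.17, 0.74, 2.15 and 2.01, so the shared slope averages unlike courses. Lysosome genes had 3 of 26 members up, CTSD, GRN and SGSH, with slopes of 0.22, 0.22 and 0.17, and autophagy genes 1 of 11, NBR1 (0.20). The camera adjusted p were 0.00442 and 0.00645, and adjusted p = 0.605 with an estimated correlation for both. SLC7A11 fell by 0.61 per doubling (SE 0.10), THBS1 by 0.37, NCEH1 by 0.32, UIMC1 by 0.32, LINC02984 by 0.30 and ODC1, the first enzyme of polyamine synthesis, by 0.27. The rows of UIMC1 differ, and averaging them turned its slope upward. Below the other genes, whose median slope was 0.046, lay 6 lists. They were G1/S and DNA replication (RRM2 fell), G2/M and mitosis, ER chaperones, NRF2 targets (SLC7A11 fell), ribosome biogenesis and YAP and cell density, with medians between -0.063 and -0.004 and adjusted p of at least 0.584 with an estimated correlation. Without the combination 48 h array the G1/S (0.014), G2/M (0.051) and NRF2 (-0.019) lists were not called, and without erlotinib 48 h the lysosome (0.077) and ribosome biogenesis (0.042) lists were not. Without combination 12 h the G2/M median was 0.004, and without erlotinib 6 h those of ribosome biogenesis and YAP were 0.023 and 0.013, while NF-kappaB targets (0.167) were called; cyclic loess ended the G1/S, G2/M and NRF2 calls (camera adjusted p = 0.102, 0.102 and 0.0594).

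In total 134 genes had a slope with time past the threshold, 118 up and 16 down, and median centring gave 126 up and 105 down. The count was 28 with no filter on the mean, 4 over all rows of the table, 14 at 1.5-fold or more, 50 with a slope per hour and 214 with a trend and robust prior. Without the combination 6 h and erlotinib 12 h arrays the count was 38. Leaving out a single array gave 863 genes without erlotinib 6 h, 86 and 48 without erlotinib 24 and 48 h, 34, 73 and 14 without quinacrine 6, 12 and 24 h, and 26, 50 and 17 without combination 6, 24 and 48 h.

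The effect of added quinacrine was tested for a change with time between combination and erlotinib. No gene passed in limma (smallest adjusted p = 0.0714), 770 genes had an unadjusted p under 0.05, and moderation with a trend and robust prior gave 16 genes. The genes nearest the threshold were CFB (difference in slope 0.93 log2 per doubling, SE 0.12, adjusted p = 0.0714), CCN3 (0.74), DNER (0.73) and F3, tissue factor (0.67). NFKB2 differed by 0.60 (SE 0.08, adjusted p = 0.0751) and TNFAIP3 by 1.01 (SE 0.18, adjusted p = 0.119). Over all genes the median difference in slope was 0.074. By list, the medians were 0.616 for interferon response and 0.254 for NF-kappaB targets, in which 15 of 17 and 6 of 18 genes passed when adjusted over the list alone. EGFR/ERK output had a median of 0.228 and cholesterol synthesis of -0.162. Camera called 10 lists, all lost with an estimated correlation (smallest adjusted p = 0.474 with an estimated correlation). It called 8 with cyclic loess and 13 with no filter on the mean. Without the combination 12 h array 24 genes passed, and without combination 48 h 2 passed.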

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

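The tests of cell cycle phases and of compressed signal, and the gene lists in the time trends, were chosen after the results were seen. Of 71 sets of 4 values examined for a value far from the others, 5 had one; chance gives about 1 in 20. On the combination 6 h array 4 measures stood apart from those of the other combination arrays: the interquartile range (2.04), the median correlation with other arrays (0.9554), the number of rows at a level of 5 or more (7470) and the median of the tested genes (6.18). CHAF1A differed by -1.85 between combination and erlotinib at 6 h, further than at the other times.

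Camera placed 10 gene lists apart from the other genes in the difference in slope between combination and erlotinib, which does not show that the effect on each list changed with time: fry, which tests whether a list moves one way on balance, called 0 of 24 lists (14 in its test of change in either direction), and no member passed over all genes. The median differences per doubling of time were as follows: interferon response 0.616, NF-kappaB targets 0.254, EGFR/ERK output 0.228, mesenchymal markers 0.191, YAP and cell density 0.12, NRF2 targets -0.021, histones -0.06, G2/M and mitosis -0.077, fatty acid synthesis -0.132 and cholesterol synthesis -0.162. Set against a median of 0.074 for all genes, camera adjusted p ran from 1.144e-08 to 0.02066, and none held with an estimated correlation (smallest adjusted p = 0.474). In 9 of the 35 regroupings of the 8 arrays camera called at least as many lists (10 in the real grouping, at most 15 in another), so chance cannot be excluded for their number; among the 8 regroupings that put 1 array of each time in each group the highest other was 14. For genes, no regrouping could give fewer than the 0 of the real grouping (35 of 35; at most 4).

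The combination 6 h array stood apart, and a compressed signal was weighed. Over all rows its difference from the other combination arrays fell by 0.1101 per log2 unit of mean level (slope -0.1101), as compression would give, but over the tested genes the slope was 0.1167. Its rows with a mean below 2 were 0.223 higher than on the other combination arrays, its tested genes below 6 differed by -0.427 and those at 6 or more differed by -0.207. The slopes had opposite signs on each of the 11 treated arrays, so their disagreement decides nothing. The erlotinib 12 h array, with no quinacrine, had the same signs to a smaller extent (-0.053 over all rows and 0.0469 over the tested genes, with rows below 2 higher by 0.127). Compression and an early response to both compounds cannot be told apart on the combination 6 h array, because it has no replicate.

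NF-kappaB targets had a median of 0.505 with the combination against erlotinib. Without the combination 6 h and erlotinib 12 h arrays, the 2 with the smallest spread of values, the list's median was 0.769, compared with 0.505 with them. That fit keeps both the combination and the erlotinib array only at 24 and 48 h, where the list's medians were 0.75 and 0.905. The 2 arrays take no part in the differences at 24 and 48 h, so the fit was bound to keep those. It shows only that the list's difference does not rest on these 2 arrays alone, and it cannot judge 6 and 12 h. The 11 members not known as induced by interferon had a median of 0.425 (95% of 10000 resamples of genes between 0.258 and 0.63), above the 0.252 set in advance as the bound. These members were thus higher too on these arrays. The resampling treats the genes as independent and leaves out the spread between arrays, so it cannot exclude that interferon-induced members account for the list's difference. In 3 of the 35 regroupings the list had as small a camera p, so chance cannot be excluded for the list as a whole. Among the 8 that put 1 array of each time in each group, too few for a share under 0.05, the camera p was 5.7e-10 in the real grouping and at least 6.55e-09 in the others. Quinacrine treatment, the difference that the design names, stays open and was not tested apart from these. Against the untreated array the list's median was -0.319 with erlotinib, 0.182 with quinacrine (not called by camera) and 0.251 with the combination. The difference of 0.505 may thus hold a fall with erlotinib, and it does not by itself show a rise caused by quinacrine.

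DNA replication genes had a median of -0.139 with the combination against erlotinib. Without the 2 arrays of smallest spread the median was -0.18, compared with -0.139. That fit keeps both the combination and the erlotinib array only at 24 and 48 h, where the list's medians were -0.115 and -0.24. These arrays take no part in the differences at 24 and 48 h, so the fit was bound to keep those. It shows only that the list's difference does not rest on these arrays alone, and it cannot judge 6 and 12 h. The G2/M median in that fit was -0.194 (camera adjusted p = 0.000795). A lower share of cycling cells in every phase cannot be told apart from a change in S-phase genes: over all arrays the G2/M median was -0.13, and resampling its genes gave -0.21 to -0.028, a range that holds the bound of -0.069. In 5 of the 35 regroupings the list had as small a camera p, so chance cannot be excluded; the smallest other among the 8 matched by time was 0.000247, below the real 0.000826.

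Regrouping was also applied to the counts. For combination versus erlotinib, 1 of 35 groupings, the real grouping, gave as many genes (212, at most 4 in another), but these groupings disregard the matching of the arrays by time. Only 8 of them put 1 array of each time in each group, too few for a share under 0.05; there the real count was 212 and the highest other 4. For lists, 22 of 35 groupings gave as many (5, at most 11 in another), so chance cannot be excluded. Interferon-response genes had as small a camera p in 10 of 35 groupings, and the smallest other among the 8 matched by time was 2.72e-12, below the real 3.67e-08. For quinacrine versus erlotinib 2 of 35 groupings gave as many genes (66; 78 in another) and 3 as many lists (11, at most 12 in another), so chance cannot be excluded over all groupings. Among the 8 matched by time, too few for a share under 0.05, the highest other was 7 genes and 7 lists. The grouping with 78 genes set erlotinib 12, 24 and 48 h against the quinacrine arrays with erlotinib 6 h, and thus moved 1 array. For combination versus quinacrine all 35 groupings gave at least the real count of 0 genes (at most 12) and 0 lists (at most 8); among the 8 matched by time the highest other was 0 genes and 3 lists.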

How the results depend on the processing

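The fit without the 2 arrays of smallest spread, and scaling of the gene lists, were chosen after the data were seen. Of 6831 values of named genes under alternatives, 6143 kept direction and side of the threshold, 503 lost and 184 gained the call, and 1 changed direction: averaging its rows gave UIMC1 a time slope of 0.046 instead of -0.317, since its 2 rows differ. Causes were not tested for the other changes, except where fewer arrays or more tested rows give them by construction.

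Combination versus erlotinib (212 genes) gave 51 with no filter on the mean, 9 over all rows of the table, 461 with cyclic loess, 439 with median centring, 380 with array weights, 6 with only the 8 arrays of the 2 groups, 34 with the 6, 12 and 24 h arrays, and 6 to 322 leaving out an array. Quinacrine versus erlotinib (66) gave 28 with no filter, 155 with a mean of at least 6, 3 over all rows, 172 with a trend and robust prior, 318 with cyclic loess, 293 with median centring, 682 with array weights, 106 with no time term, 41 with the 6, 12 and 24 h arrays, and 0 to 288 leaving out an array. Combination versus quinacrine gave 0 genes under every alternative run. Erlotinib versus untreated (0) gave 1 with no filter and 2 over all rows. Quinacrine versus untreated (2) gave 6 with median centring, 494 with array weights, 9 without the 2 arrays, and 0 to 5 leaving out an array. Combination versus untreated (3) gave 1 over all rows, 6 with median centring, 809 with array weights, 5 without the 2 arrays, and 0 to 5 leaving out an array. The departure from additivity (0) gave 1 with no filter and 1 over all rows. The time trend (134) gave 28 with no filter, 4 over all rows, 214 with a trend and robust prior, 231 with median centring, 14 at 1.5-fold or more, 38 without the 2 arrays, 50 with a slope per hour, and 14 to 863 leaving out an array. The difference in time trend (0) gave 3 with a mean of at least 6, 16 with a trend and robust prior, and 0 to 24 leaving out an array.

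With an estimated correlation camera called 0 lists in every comparison. With no filter it called 15 lists for combination versus erlotinib (5), 1 for combination versus quinacrine (0), 1 for erlotinib versus untreated (5), 7 for quinacrine versus untreated (0) and 10 for combination versus untreated (6). Without the 2 arrays it called 9 for combination versus erlotinib, 7 for quinacrine versus erlotinib (11), 1 for combination versus quinacrine and 2 for quinacrine versus untreated. With no time term it called 2 for quinacrine versus erlotinib and 1 for combination versus quinacrine. Cyclic loess and median centring each called 1 for quinacrine versus untreated. The replicate numbers follow accession order and pair no samples. The time labels match the treated arrays, and time stood as a factor in the fit of the 11 treated arrays. The fit of the 2 groups alone (6 genes) is matched by time as well, and it takes its spread from the erlotinib and combination arrays only. Signal over background limits genes below a mean of 5, which were not tested, and levels near it in 1 group give folds that background can shrink.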

Other observations

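Heat shock genes, 8 of which were tested, had a median of -0.297 in the combination arrays and -0.262 in the quinacrine arrays against the untreated array. The test of fry, which asks whether members move one way on balance, called the list lower in both (adjusted p = 0.00169 and 0.00506), and also in combination against erlotinib (median -0.103, adjusted p = 0.00283), where camera gave adjusted p = 0.109. Camera at its preset correlation did not call the list for quinacrine against untreated (adjusted p = 0.0687), and with an estimated correlation it called it in none of these 3 comparisons (adjusted p = 0.634, 0.809 and 0.615). DNAJA1 differed from the untreated array by -0.39, -0.45, -0.45 and -0.46 at 6, 12, 24 and 48 h of the combination. With erlotinib alone it was also below the untreated level of 8.31, at 8.05, 7.79, 7.83 and 8.01. DNAJB1 fell 1.56-fold against erlotinib.

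Lists of lipid synthesis genes were also read at each time. The median of 14 cholesterol synthesis and uptake genes against erlotinib was 0.085 at 6 h, 0.6 at 12 h, 0.45 at 24 h and -0.415 at 48 h, and in the quinacrine arrays it was 0.17, 0.6 and 0.3 at 6, 12 and 24 h. The 7 fatty acid synthesis genes had -0.25, 0.19, -0.16 and -0.69 in the combination arrays against erlotinib. Against the untreated array they had -0.13, 0.12, 0.15 and -0.09 with the combination and -0.01, -0.1, 0.21 and 0.57 with erlotinib. FASN, fatty acid synthase, chosen here after its value was seen, had a log2 difference of -0.62 (SE 0.10, limma adjusted p = 0.0242). These courses rest on 1 array per time and are not set against the other tested genes. The median over all tested genes against the untreated array was -0.21 on combination 6 h. The marker sets of fibroblasts and endothelial cells had no gene past the filter, with median levels of 1.22 and 1.56, and of 7 immune markers 3 passed it (median level 1.79).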
